A study of Homo sapiens with 18 samples.

How the data were processed

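RNA was sequenced from 18 libraries of CAL51 cells, a cell line established from a breast carcinoma. The labels put 3 libraries in each of 6 groups: wild type (WT) and cells labelled as knockouts of PEX26, GOLGA5, SEC61A2, GOLGA8M or SEC62. Per the labels, a guide RNA vector with Cas9 was transfected, single GFP-positive cells were sorted after 3 days to found colonies, and edited alleles were checked by Sanger sequencing. The labels give neither the number of colonies behind a group nor whether replicates are separate cultures of 1 colony, so a p-value here measures the spread between these libraries, and colony and knockout coincide. The series design text speaks of mice and of SEC61, whereas the sample labels say human CAL51 cells and SEC62; the sample labels were followed.

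The authors named Trim Galore 0.6.6, cutadapt 1.18, FastQC 0.11.9, STAR 2.7.8a, Salmon 1.3.0, DESeq2 1.26.0 and the human genome build GRCh38. The 5 tables deposited by the authors, 1 per knockout, hold a signal per gene and library in normalised counts: read counts divided by a factor for each library and gene. The 3 WT libraries occur in each table with other values, so each table was normalised on its own and tests were run within a table only. Whole reads could not be recovered. The authors also deposited 5 comparison tables with, per the file headers, a log2 fold change and its standard error (log2), and an s-value between 0 and 1, a probability of a wrong sign or a change under the fold minimum that takes the place of a p-value. Whether these fold changes were shrunken is not stated.

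Each table has 60664 rows keyed by Ensembl gene identifier. A gene name table gave symbols to 41986 rows, GENCODE 29 alone to 16483, the files themselves to 35 mitochondrial rows, and 2160 rows had none. Positions are those of GENCODE 29 on GRCh38; the release that the authors used is not stated.

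Column totals lay between 25.2 M and 32.2 M normalised counts (M, mega). The spacing of the low values gave the approximate value of 1 read, 0.650 to 1.28 normalised counts, and from it an approximate depth of 23.6 M to 31.2 M reads in WT and 21.8 M to 49.5 M in the knockout libraries. The 10 highest genes took 5.34% to 8.88% of a column total.

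For each knockout, genes with a mean of at least 10 normalised counts over the 6 libraries of the table were tested on log2(value + 1) with limma 3.58.1 (limma-trend, two-sided) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are knockout minus WT with their standard error (SE); levels are means with the standard deviation (SD) of 3 libraries. The procedure was tested on simulated data with 3 libraries per group. It recovered 89.9% to 98.0% of genes changed by 1 log2 unit and at least 99.0% of genes changed by 2. Of its calls, 2.59% to 5.53% were unchanged genes. Each simulated table had 96 to 100 genes changed at each size and 1 common extra spread for all genes. In the real tables far more genes changed and spreads were uneven, so these rates need not hold there.

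The tests, most alternatives, the rule for naming genes and 40 gene lists of 13 to 77 genes were fixed before the data were examined. The list tests under another pseudocount, under other filters and without single libraries were added later, and the tests of what lies behind a pattern were chosen after the results were seen. The lists cover organelles, lipid metabolism, stress responses, immune genes, growth, cell identity, markers of other cell types and library quality. A list with at least 3 tested members was tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, again with an estimated correlation, and with fry. The genes named are the 5 targets and 4 relatives, the 6 highest and 6 lowest called genes with a mean of at least 100 counts, 4 members of each of the 3 leading lists, and the 6 highest and 6 lowest genes called alike in all 5 comparisons. Further members of gene lists, called or not, are given as examples; those were chosen after their values were seen.

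Genes changed in several knockouts were counted over the 14853 genes tested in all 5 tables. Because the comparisons share their WT libraries, the covariance of log2 fold changes between comparisons was set beside 100 simulated draws in which no gene changed and the WT libraries were shared. The alternatives were another pseudocount, other filters, TMM factors, the replicate number as a block, a stricter threshold and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. No library was left out.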

Results

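RNA sequencing measured transcript levels in 18 libraries of CAL51 cells, 3 from wild-type (WT) cells and 3 from each of 5 knockouts, labelled PEX26, GOLGA5, SEC61A2, GOLGA8M and SEC62. Each knockout was compared with the same 3 WT libraries, which asks how transcript levels differ when a gene of peroxisomes, of the Golgi or of the protein entry route of the endoplasmic reticulum has been targeted. Levels are mean normalised counts ± SD and log2 fold changes (knockout over WT) are given ± SE, with n = 3 libraries per group throughout. Column totals were 25.2 M to 32.2 M normalised counts (M, mega). Libraries of 1 group correlated across genes at r = 0.97 to 0.98, and a WT with a knockout library at 0.90 to 0.93.

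PEX26 (chromosome 22, 18077920 to 18131138; ENSG00000215193.14), the membrane anchor of the PEX6 ATPase on peroxisomes, stood at 1454, 1620 and 1743 counts in the WT libraries and at 593, 601 and 511 in the PEX26 knockout libraries, which is 0.354 of WT (limma, adjusted p = 6.43e-05). GOLGA5 (chromosome 14, 92794231 to 92839963; ENSG00000066455.13), the golgin also called golgin-84, was at 1137, 1226 and 1026 counts in WT and at 112, 122 and 166 in its knockout (-3.09 ± 0.17, adjusted p = 1.11e-05). SEC61A2 (chromosome 10, 12129637 to 12169961; ENSG00000065665.21), which encodes an alpha subunit of the Sec61 translocon, was higher in the libraries labelled SEC61A2 knockout: 424, 449 and 403 counts in WT against 1351, 1523 and 1547 (1.79 ± 0.11, adjusted p = 1.24e-05). SEC62 (chromosome 3, 169966635 to 169998373; ENSG00000008952.17), a translocation factor of the endoplasmic reticulum, did not pass in its own knockout, with 3355 ± 144 counts in WT and 2935 ± 283 in the knockout (-0.20 ± 0.11, adjusted p = 0.219), so its label cannot be checked from its transcript level. GOLGA8M (chromosome 15, 28701954 to 28738384; ENSG00000188626.6), a golgin-like gene in a cluster of near-identical copies, had a mean of 1.29 ± 1.42 counts in WT and 1.57 ± 2.73 in its knockout and was too low to test, which leaves its label unchecked too.

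Among the relatives of the targets, SEC63, the partner of SEC62, fell in the GOLGA5 knockout from 2956 ± 161 to 1635 ± 135 counts (-0.86 ± 0.10, adjusted p = 7.35e-04). GOLGA8B rose in the GOLGA8M knockout from 1207 ± 89.6 to 1840 ± 273 counts (0.60 ± 0.13, adjusted p = 0.0117). SEC62 fell in the PEX26 knockout (-0.32 ± 0.09, adjusted p = 0.0395) and rose in the GOLGA8M knockout (0.44 ± 0.11, adjusted p = 0.0236). Neither SEC62 call held without WT replicate 1, where adjusted p was 0.0951 and 0.0529. Leaving out other libraries also ended them, with adjusted p up to 0.129 in the PEX26 and 0.0768 in the GOLGA8M knockout, and in the PEX26 knockout so did no filter (0.0590) and a replicate block (0.0985). SEC61A1 and GOLGA8A did not pass in any of the 5 comparisons.

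**Figure D1:**
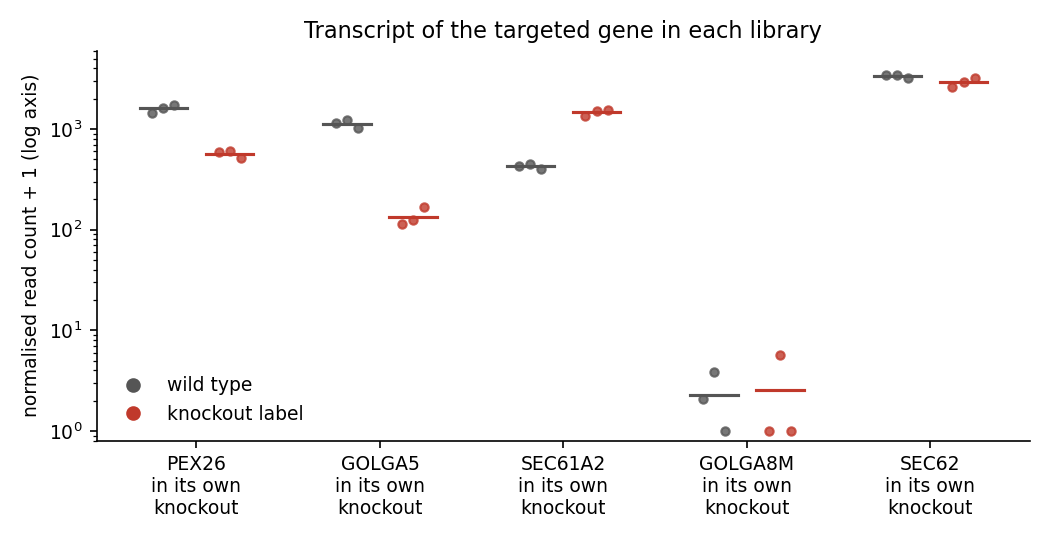
Normalised read count plus 1 (log axis) of each targeted gene in its own comparison, 1 point per library, with a bar at the mean of the 3 WT (grey) and 3 knockout (red) libraries. PEX26 and GOLGA5 lie lower in their knockouts, SEC61A2 lies higher at 1351 to 1547 counts, SEC62 differs by -0.20 log2 units, and GOLGA8M is near 0 in both groups.

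Between 22.1% and 34.8% of the tested genes differed from WT. In the PEX26 knockout 3937 of 15805 genes changed (1954 higher, 1983 lower). In the GOLGA5 knockout it was 3409 of 15434 (1722 higher, 1687 lower) and in the libraries labelled SEC61A2 knockout 5572 of 16001 (2847 higher, 2725 lower). In the GOLGA8M knockout 3823 of 15314 genes changed (1872 higher, 1951 lower) and in the SEC62 knockout 4091 of 15748 (1870 higher, 2221 lower). At an adjusted p under 0.01 and a change of at least 1 log2 unit these counts were 1355, 1067, 2110, 1221 and 1596. At this threshold 632 were higher and 723 lower (PEX26), 500 and 567 (GOLGA5) and 1235 and 875 (SEC61A2 label). For GOLGA8M it was 582 and 639, and for SEC62 550 and 1046. The GOLGA5 count at an adjusted p under 0.05 was 2270 without WT replicate 2. The names of the authors' deposited comparison tables give a fold minimum of 1 log2 unit. At an s-value under 0.01 these tables call 1123, 817, 1692, 888 and 1319 genes. Of these, 1053, 757, 1572, 837 and 1241 passed the filter and were tested here. At an adjusted p under 0.05, which sets no fold minimum, 1051, 755, 1567, 835 and 1239 of them also changed here. Of the genes called here at the stricter threshold, 1016, 734, 1526, 811 and 1183 were also called by the authors. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold changes in the authors' deposited tables with those computed here was 0.980 to 0.991.

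**Figure D2:**
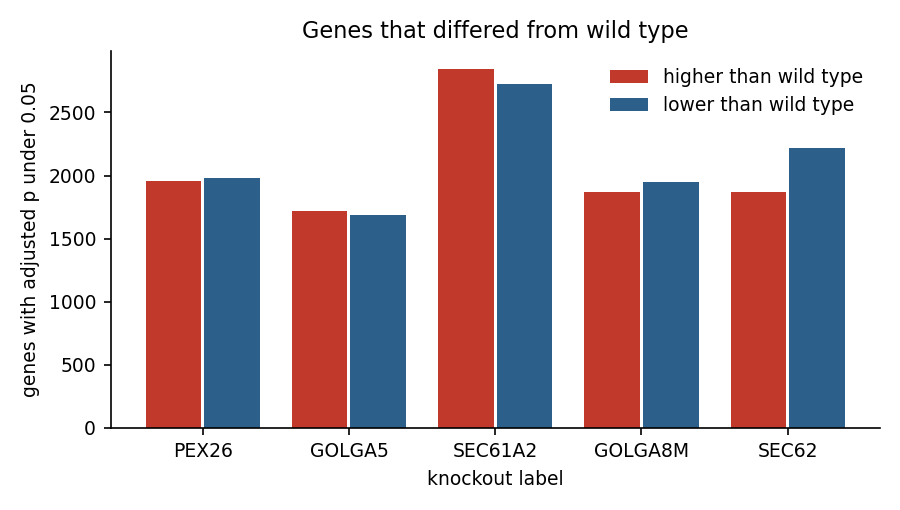
Number of genes with an adjusted p under 0.05 in each of the 5 comparisons with WT, split into genes higher (red) and lower (blue) than WT. The libraries labelled SEC61A2 knockout have the most, with 2847 higher and 2725 lower, and the GOLGA5 knockout the fewest, with 1722 and 1687.

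In the PEX26 knockout, SEMA6A, a semaphorin, rose from 41.4 ± 19.4 to 3353 ± 163 counts, and SLCO2A1, a prostaglandin transporter, from 18.6 ± 1.41 to 1470 ± 94.1. The kallikrein protease genes KLK11 and KLK8 rose, the first from 3.71 ± 1.07 to 242 ± 16.2 and the second from 12.5 ± 7.64 to 480 ± 55.5 counts. CRYM, a thyroid hormone binding protein, rose from 12.7 ± 3.08 to 656 ± 84.6, and the long noncoding RNA XACT from 20.5 ± 26.7 to 360 ± 31.3. SHISA9 fell from 1999 ± 427 to 0.392 ± 0.341 counts and FXYD5, a regulator of the sodium pump, from 845 ± 37.1 to 0.842 ± 1.46. DPP4, a cell surface peptidase, BMP5, a bone morphogenetic protein, CHST15, a sulfotransferase, and GAGE2A, a cancer-testis antigen gene, stood at 782 ± 88.8, 757 ± 41.1, 606 ± 23.9 and 574 ± 90.3 counts in WT. All 4 were listed at 0 in all 3 knockout libraries. Each of these 12 genes had an adjusted p of at most 0.00948. XACT was uneven in WT (50.7, 0.424 and 10.3 counts), and its log2 fold change of 5.26 ± 1.08 was 6.49 without WT replicate 1 and 3.90 without WT replicate 2. The authors' deposited table gives XACT 2.85, with an s-value of 0.0298.

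Among the 16 measured peroxins of the PEX26 knockout, PEX6, whose protein binds PEX26, rose from 543.6 to 885 ± 22.5 counts (0.70 ± 0.10). PEX26 and PEX10 fell, PEX10 by -0.35 ± 0.08, and 13 did not pass (camera adjusted p = 0.895). Of 40 measured genes of peroxisomal metabolism, 11 rose, 4 fell and 25 did not pass, with 11 up and 5 down when adjusted over the list alone. The list did not pass (camera adjusted p = 0.168). CAT, the catalase, rose by 0.72 ± 0.10, PHYH, the phytanoyl-CoA hydroxylase, to 410.1 ± 37.4 counts and CROT, a carnitine transferase, by 0.97 ± 0.12. PXMP4, a peroxisomal membrane protein, fell by -0.75 ± 0.18.

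Of 24 measured p53 targets in the PEX26 knockout, 18 rose, 0 fell and 6 did not pass, and 20 rose when adjusted over the list alone (camera adjusted p = 4.08e-08, adjusted p = 0.187 with an estimated correlation). PHLDA3 rose by 1.34 ± 0.29, FAS, a death receptor, by 1.21 ± 0.25, and BAX, which permeabilises mitochondria in apoptosis, by 1.05 ± 0.09. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 2367 ± 156 to 4713 ± 144 counts. Mitotic genes fell, 10 of 34 with 24 that did not pass, and again 10 when adjusted over the list alone (camera adjusted p = 8.07e-04, adjusted p = 0.419 with an estimated correlation). MKI67 fell by -0.79 ± 0.13, CENPA, the centromeric histone, by -0.75 ± 0.12, CDC25C by -0.68 ± 0.11 and ASPM by -0.66 ± 0.14. Of 43 genes of DNA replication 9 fell and 34 did not pass, 9 also when adjusted over the list alone (camera adjusted p = 0.0365, adjusted p = 0.419 with an estimated correlation). GINS2 fell by -0.48 ± 0.09, E2F2 by -0.48 ± 0.09, E2F1 by -0.55 ± 0.14 and CHAF1B by -0.64 ± 0.16. The E2F1 and CHAF1B calls did not hold without PEX26 knockout replicate 3 (adjusted p = 0.0702 and 0.0638). E2F1 was also lost without WT replicate 2 (0.0808) or 3 (0.0712) and with a replicate block (0.0518), and CHAF1B without knockout replicate 1 (0.0742).

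Of 32 targets of ATF4, a transcription factor of the integrated stress response, 14 fell and 5 rose in the PEX26 knockout, and 15 fell and 6 rose when adjusted over the list alone (camera adjusted p = 0.0365, adjusted p = 0.419 with an estimated correlation). STC2 fell by -1.90 ± 0.21 and ASNS, the asparagine synthetase, by -0.98 ± 0.10, while VLDLR rose by 0.95 ± 0.20. Epithelial genes fell on balance, 14 lower and 4 higher of 30 (14 and 5 when adjusted over the list alone), with camera adjusted p = 0.0365 and adjusted p = 0.468 with an estimated correlation. LAMB3, a laminin chain, fell by -4.70 ± 0.40 and ITGB4, an integrin, by -4.86 ± 0.36. CD24 rose by 5.18 ± 0.12 and KRT19 by 1.80 ± 0.13. Genes of Golgi glycosylation rose, 12 of 51 with 3 lower (13 and 3 when adjusted over the list alone), among them the sialyltransferase ST6GAL1 by 2.81 ± 0.36 and the fucosyltransferase FUT8 by 1.01 ± 0.11 (camera adjusted p = 0.0471, adjusted p = 0.468 with an estimated correlation). Markers of muscle and adipocytes moved with these groups: 4 of 8 fell, 5 with 1 higher when adjusted over the list alone, including TNNT2, a cardiac troponin, by -2.06 ± 0.12 (camera adjusted p = 0.0365, adjusted p = 0.419 with an estimated correlation). The Golgi call did not hold without WT replicate 1 (0.108) or 2 (0.0519). The epithelial call was lost without WT replicate 3 (0.0520) or with only genes of mean 50 or more (0.367). The muscle call was lost without WT replicate 1 (0.0505) or 3 (0.0565) or knockout replicate 3 (0.0531).

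In the GOLGA5 knockout, KIF1A, a kinesin of axonal transport, rose from 8.03 ± 6.19 to 5964 ± 3761 counts and DMD, which encodes dystrophin, from 3.14 ± 2.11 to 1779 ± 271. C4orf19 rose from 2.51 ± 2.74 to 288 ± 41.6, OLFML2B from 19.96 ± 4.57 to 1271 ± 305 and PKNOX2, a homeobox factor, from 4.89 ± 1.55 to 321 ± 69.9. ISY1-RAB43, a read-through of the genes ISY1 and RAB43, was listed at 0 in WT and at 507, 18.6 and 1242 counts in the knockout libraries. Its log2 fold change of 7.854 was 5.627 with pseudocount 5, 9.635 without knockout replicate 2 and 6.641 without knockout replicate 3. SPP1, which encodes osteopontin, fell from 5626 ± 492 to 1.43 ± 0.312 counts. DPP4, BMP5, KLHL14, GAGE2A and CDHR1 stood at 678 ± 76.2, 656.5 ± 36.1, 609 ± 22.3, 498 ± 77.8 and 499 ± 123 counts in WT and were listed at 0 in all 3 knockout libraries. Each of these 12 genes had an adjusted p of at most 0.00363. The KIF1A log2 fold change of 9.34 was 10.11 without knockout replicate 3 and 8.674 without WT replicate 1. That of C4orf19 moved from 6.626 to 7.225 without WT replicate 2.

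Lysosomal genes rose together in the GOLGA5 knockout: of 58 measured, 33 rose, 1 fell and 24 did not pass, and 39 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.83e-10, adjusted p = 0.164 with an estimated correlation). The sulfatase ARSB rose from 1788 ± 58.8 to 6322 ± 370 counts, the cathepsin CTSV from 445 ± 48.2 to 1218 ± 58.5 and the cholesterol transfer protein NPC2 from 1323 ± 95.3 to 3459 ± 358. MITF, a transcription factor that drives lysosomal genes, rose by 0.96 ± 0.22. That call did not hold without WT replicate 1 (adjusted p = 0.0595) or 2 (0.0617) or knockout replicate 2 (0.0537). NPC1, the membrane partner of NPC2, fell by -0.57 ± 0.12. Golgins and Golgi matrix genes went both ways, 3 higher, 3 lower and 24 not passed of 30 (camera adjusted p = 0.492). GOLIM4 rose by 1.14 ± 0.15 and GOLGA2, which encodes the matrix protein GM130, by 0.75 ± 0.10, while ACBD3 fell by -1.26 ± 0.27.

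Mitochondrial ribosomal protein genes fell in the GOLGA5 knockout, 15 of 77 with 62 that did not pass, 10 when adjusted over the list alone (camera adjusted p = 3.75e-06, adjusted p = 0.164 with an estimated correlation). MRPS5 fell by -0.92 ± 0.10, MRPS15 by -0.67 ± 0.17, MRPS27 by -0.54 ± 0.14 and MRPS9 by -0.53 ± 0.12. Of 49 genes of mitochondrial import and dynamics, 11 fell, 0 rose and 38 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 6.78e-04, adjusted p = 0.164 with an estimated correlation). HSPD1, the matrix chaperonin, fell by -0.67 ± 0.12. Cytosolic ribosomal protein genes had a median of -0.16, with 5 of 76 lower and 0 when adjusted over the list alone (camera adjusted p = 1.20e-04, adjusted p = 0.377 with an estimated correlation). RPLP0 fell by -0.64 ± 0.13, RPL38 by -0.44 ± 0.11, RPL23A by -0.35 ± 0.08 and RPS27A by -0.34 ± 0.08. Of the 34 proteasome genes 2 fell, PSMD3 and PSMA4, and 0 when adjusted over the list alone (camera adjusted p = 0.00444, adjusted p = 0.164 with an estimated correlation). Of these 8 ribosomal genes, MRPS15, MRPS27, RPL38, RPL23A and RPS27A lost their call without WT replicate 2 (adjusted p = 0.0693, 0.0990, 0.0750, 0.0624 and 0.0796). MRPS9 lost it without WT replicate 1 (0.0549), and each of these 6 also without at least 1 further library. RPL38 and RPS27A also lost it with a replicate block (0.0533 and 0.0562), and RPS27A with no filter (0.0536).

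Several stress lists moved in the GOLGA5 knockout. Of 21 heat shock genes 10 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.00262, adjusted p = 0.164 with an estimated correlation), among them the chaperones HSPA8 by -0.62 ± 0.10 and HSP90AB1 by -0.58 ± 0.09. Of 24 targets of NRF2, the transcription factor of antioxidant genes, 11 fell and 1 rose, and 12 and 1 when adjusted over the list alone, including TALDO1 by -0.91 ± 0.09 (camera adjusted p = 0.00477, adjusted p = 0.164 with an estimated correlation). ATF4 targets fell on balance, 11 lower and 3 higher of 32, the same when adjusted over the list alone, with CTH at -2.03 ± 0.14 (camera adjusted p = 0.0180, adjusted p = 0.164 with an estimated correlation). Chaperones and degradation genes of the endoplasmic reticulum rose, 9 of 32 with 1 lower (10 and 3 when adjusted over the list alone), with XBP1 at 0.53 ± 0.09 (camera adjusted p = 0.0129, adjusted p = 0.240 with an estimated correlation). Immediate early genes rose, 11 of 26 with 3 lower (15 and 3 when adjusted over the list alone), with EGR1 at 2.80 ± 0.14 and FOSL1 at -2.91 ± 0.21 (camera adjusted p = 0.00230, adjusted p = 0.164 with an estimated correlation).

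Epithelial genes fell in the GOLGA5 knockout, 15 of 30 with 5 higher (15 and 6 when adjusted over the list alone), at camera adjusted p = 0.00230 and adjusted p = 0.164 with an estimated correlation. KRT19 fell from 519 to 4.84 ± 0.340 counts (-6.48 ± 0.20) and LAMA3 by -6.81 ± 0.48, while DSP, the desmosomal desmoplakin, rose by 2.09 ± 0.10. Of 4 measured neural markers 3 rose, also when adjusted over the list alone: SNAP25 by 2.31 ± 0.32, TUBB3 by 2.13 ± 0.11 and MAP2 by 0.75 ± 0.10 (camera adjusted p = 0.00262, adjusted p = 0.210 with an estimated correlation). The epithelial call did not hold with only genes of mean 50 or more (0.0745), nor the neural call with no filter (0.0578).

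In the libraries labelled SEC61A2 knockout, PRRX1, a homeobox factor of mesenchyme, rose from 0.333 ± 0.577 to 2085 ± 304 counts, and MYOCD, the smooth muscle coactivator myocardin, from 1.05 ± 1.82 to 2123 ± 44.5. DMD rose from 3.32 ± 2.23 to 3456 ± 328, CLMP, an adhesion molecule, from 0.537 ± 0.465 to 1186 ± 96.9. A2M, a protease inhibitor, rose from 11.6 ± 8.08 to 7434 ± 283, and BGN, the matrix proteoglycan biglycan, from 64.9 ± 8.11 to 28720 ± 2723. PKHD1L1 fell from 693 ± 96.2 to 0.224 ± 0.387 counts, STK32B, a kinase, from 616 ± 106 to 0.595 ± 0.515 and BMP5 from 738 ± 40.7 to 3.54 ± 1.56. GAGE2A, IFT27, a subunit of the intraflagellar transport complex, and GAGE2E stood at 538 ± 84.9, 459 ± 50.5 and 318 ± 136 counts in WT. They were listed at 0 in all 3 libraries with this label. Each of these 12 genes had an adjusted p of at most 5.12e-06.

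Mesenchymal and matrix genes rose with this label: of 40 measured, 24 rose, 6 fell and 10 did not pass, and 25 and 6 when adjusted over the list alone (camera adjusted p = 8.54e-05, adjusted p = 0.136 with an estimated correlation). FN1, which encodes fibronectin, rose from 7242 ± 458.5 to 118800 ± 5501 counts and SPARC from 2565 ± 209 to 18260 ± 781. SNAI2, a repressor of epithelial genes, and TIMP3 were listed at 0 in WT and stood at 220.3 ± 20.1 and 63.5 ± 3.91 counts. COL1A2 and CD44 fell, by -2.03 ± 0.16 and -3.36 ± 0.26. Of 30 epithelial genes 21 fell, 3 rose and 6 did not pass, the same 21 and 3 when adjusted over the list alone (camera adjusted p = 2.57e-06, adjusted p = 0.136 with an estimated correlation). LAMA3 fell by -6.43 ± 0.68, KRT19 by -5.64 ± 0.31, LAMB3 by -5.02 ± 0.66 and ITGB4 by -4.43 ± 0.40. LAMA3 was at -5.54 without knockout replicate 1 and at -7.05 without knockout replicate 3, and LAMB3 at -5.89 without the latter. Of 20 targets of YAP 14 rose and 2 fell, and 15 and 2 when adjusted over the list alone, with CCN2 at 3.38 ± 0.13 (camera adjusted p = 9.76e-05, adjusted p = 0.136 with an estimated correlation).

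Markers of other cell types moved with these groups. Of 8 endothelial markers above the filter 6 rose and 1, EGFL7, fell, the same when adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.136 with an estimated correlation). TIE1, an endothelial receptor, rose from 4.18 to 1752 ± 280 counts and PLVAP from 2.00 to 299 ± 12.8. The other 6 of the 14 markers listed were below the filter. Muscle and adipocyte markers fell, 5 of 7 with CKM higher (6 and 1 when adjusted over the list alone), with TNNT2 at -3.11 ± 0.14 (camera adjusted p = 0.00545, adjusted p = 0.146 with an estimated correlation). Of 3 neural markers TUBB3 and MAP2 rose, by 0.89 ± 0.09 and 1.17 ± 0.09, also when adjusted over the list alone (camera adjusted p = 0.0489, adjusted p = 0.391 with an estimated correlation). This list call did not hold with pseudocount 5 (0.05002), TMM factors (0.0508), a replicate block (0.0696) or no filter (0.677), nor without WT replicate 3 (0.0721) or without knockout replicate 2 (0.0783). Of 10 histone genes listed as having messages without poly(A) tails 5 rose and 0 fell, also when adjusted over the list alone. H2BC4 rose by 1.66 ± 0.26. This histone list did not pass (camera adjusted p = 0.0827).

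Mitotic genes fell in the libraries labelled SEC61A2 knockout, 24 of 34 with 0 higher and 10 that did not pass, and 28 when adjusted over the list alone (camera adjusted p = 4.51e-08, adjusted p = 0.136 with an estimated correlation). KIF20A, a mitotic kinesin, fell by -1.22 ± 0.10, HMMR by -1.05 ± 0.17, MKI67 by -0.94 ± 0.12 and TTK by -0.86 ± 0.11. DNA replication genes fell, 15 of 43 with 2 higher (17 and 2 when adjusted over the list alone), with RFC3 at -0.85 ± 0.13 (camera adjusted p = 0.00466, adjusted p = 0.136 with an estimated correlation). Of 33 nuclear pore and lamina genes 8 fell, also when adjusted over the list alone, NUP160 and NUP210 by -1.45 ± 0.09 and -1.45 ± 0.11 (camera adjusted p = 0.00466, adjusted p = 0.136 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 10 fell, 3 when adjusted over the list alone, RPS21 by -0.45 ± 0.08 (camera adjusted p = 0.00839, adjusted p = 0.354 with an estimated correlation). The p53 targets rose, 13 of 24 with 2 lower (15 and 2 when adjusted over the list alone), CDKN1A by 1.44 ± 0.09 (camera adjusted p = 0.00826, adjusted p = 0.354 with an estimated correlation). Immediate early genes rose, 14 of 26 with 4 lower, the same when adjusted over the list alone, EGR1 by 3.14 ± 0.13 (camera adjusted p = 0.00466, adjusted p = 0.428 with an estimated correlation). The 39 genes of translocation into the endoplasmic reticulum did not pass as a list, with 4 higher and 4 lower (camera adjusted p = 0.899). TRAM2 rose by 0.85 ± 0.08 and SEC11A, a signal peptidase subunit, fell by -0.75 ± 0.11.

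In the GOLGA8M knockout, ABI3BP rose from 8.42 ± 3.14 to 890.3 ± 73.5 counts, KLHL13 from 9.17 ± 8.16 to 458.5 ± 102, ISLR from 12.1 ± 6.08 to 565.5 ± 27.7 and JPH4, a junctophilin, from 18.3 ± 9.79 to 462 ± 43.7. DHRS2, a short-chain dehydrogenase, rose from 1869 ± 88.1 to 55500 ± 7283 counts. ISY1-RAB43 was listed at 0 in WT and at 10.6, 1153 and 258 counts in the knockout libraries. Its log2 fold change of 7.242 was 5.071 with pseudocount 5, 9.094 without knockout replicate 1 and 5.776 without knockout replicate 2. SPP1 fell from 9038 ± 786 to 5.35 ± 2.29 counts and COL1A2, a chain of type I collagen, from 11540 ± 2420 to 8.52 ± 0.798. BCAT1, a branched-chain aminotransferase, fell from 1063 ± 93.9 to 0.483 ± 0.837 and PRUNE2 from 931 ± 88.7 to 0.496 ± 0.438. DACH1, a transcription factor, and DPP4 stood at 996 ± 25.8 and 645 ± 72.3 counts in WT and were listed at 0 in all 3 knockout libraries. Each of these 12 genes had an adjusted p of at most 0.00693. The KLHL13 log2 fold change of 5.858 was 6.501 without WT replicate 2 and 5.14 without WT replicate 3.

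Mitotic genes fell in the GOLGA8M knockout, 27 of 34 with 0 higher and 7 that did not pass, and 29 when adjusted over the list alone (camera adjusted p = 4.91e-12, adjusted p = 0.111 with an estimated correlation). TOP2A, a topoisomerase, fell by -1.35 ± 0.10, CENPE by -1.23 ± 0.17, HMMR by -1.03 ± 0.18 and BUB1 by -0.93 ± 0.14. Of 43 DNA replication genes 2 rose and 3 fell (camera adjusted p = 0.951). The p53 targets rose, 15 of 25 with 1 lower (17 and 1 when adjusted over the list alone), at camera adjusted p = 2.24e-07 and adjusted p = 0.172 with an estimated correlation. CDKN1A rose from 1899 ± 123 to 6529 ± 380.5 counts, EDA2R by 3.31 ± 0.49, FAS by 2.92 ± 0.24 and ZMAT3 by 1.74 ± 0.12. With pseudocount 5 EDA2R was at 2.56.

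Antigen presentation genes rose in the GOLGA8M knockout, 11 of 14 with 0 lower and 3 that did not pass, 11 also when adjusted over the list alone (camera adjusted p = 1.47e-06, adjusted p = 0.155 with an estimated correlation). NLRC5, a transactivator of MHC class I genes, rose by 1.95 ± 0.40, the immunoproteasome subunits PSMB8 and PSMB9 by 1.75 ± 0.14 and 1.32 ± 0.27, and the peptide transporter TAP1 by 1.42 ± 0.12. Of 19 inflammatory genes 11 rose and 3 fell, also when adjusted over the list alone, with TNFAIP3 at 1.15 ± 0.14 and CXCL8 at -3.30 ± 0.49 (camera adjusted p = 0.00746, adjusted p = 0.246 with an estimated correlation). With no filter the list did not pass (0.151). Of 24 immediate early genes 10 rose and 0 fell, and 10 and 1 when adjusted over the list alone, with DUSP1 at 1.45 ± 0.13 (camera adjusted p = 0.00457, adjusted p = 0.317 with an estimated correlation). Cholesterol synthesis genes fell, 11 of 25 with 2 higher (12 and 2 when adjusted over the list alone): SQLE, the squalene epoxidase, by -1.01 ± 0.14 (camera adjusted p = 0.00695, adjusted p = 0.475 with an estimated correlation). ATF4 targets fell on balance, 15 lower and 5 higher of 32 (16 and 5 when adjusted over the list alone), with ASNS at 1044 ± 116.5 counts against 2085 ± 46.4 in WT (camera adjusted p = 0.0236, adjusted p = 0.251 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 8 rose, 5 when adjusted over the list alone, RPL10 by 0.56 ± 0.09 (camera adjusted p = 2.64e-04, adjusted p = 0.613 with an estimated correlation). Golgins and Golgi matrix genes did not pass as a list, with 2 higher and 3 lower of 31 (camera adjusted p = 0.726). GOLIM4 fell by -0.66 ± 0.10.

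In the SEC62 knockout, CDX2, an intestinal homeobox factor, rose from 1.22 ± 2.12 to 567 ± 39.5 counts and CXCL5, a chemokine, from 11.9 ± 3.57 to 1537 ± 291.5. MEF2C, a transcription factor of muscle and neurons, rose from 10.6 ± 11.04 to 911 ± 113, C2orf72 from 3.42 ± 2.56 to 429.6 ± 83.6, the long noncoding RNA LINC00261 from 1.70 ± 2.47 to 199.5 ± 39.3 and NIBAN1 from 104 ± 10.8 to 5199 ± 391. FGF2, a fibroblast growth factor, fell from 1264 ± 92.4 to 1.25 ± 0.402 counts, CHST15 from 695 ± 28.4 to 0.424 ± 0.735 and PKHD1L1 from 813 ± 113 to 0.875 ± 0.990. DPP4, GAGE2A and HORMAD1, a meiotic protein gene, stood at 776 ± 88.0, 569.5 ± 88.8 and 536 ± 35.7 counts in WT and were listed at 0 in all 3 knockout libraries. Each of these 12 genes had an adjusted p of at most 1.93e-04. Without WT replicate 1, the log2 fold change of CDX2 moved from 8.407 to 9.148. MEF2C moved there from 6.733 to 7.486 and LINC00261 from 6.587 to 7.3.

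Targets of ATF4 rose in the SEC62 knockout: of 32 measured, 25 rose, 1 fell and 6 did not pass, and 26 and 1 when adjusted over the list alone (camera adjusted p = 3.32e-13, adjusted p = 0.0951 with an estimated correlation). CHAC1, an enzyme of glutathione breakdown, rose from 343 ± 24.5 to 1999 ± 68.5 counts, STC2 from 1234 ± 266 to 6093 ± 965, GDF15, a stress cytokine, from 625 ± 120 to 2957 ± 459 and NUPR1 from 79.5 ± 8.12 to 312 ± 33.5. Of 25 NRF2 targets 13 rose and 3 fell, and 14 and 5 when adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.203 with an estimated correlation). SLC7A11, the cystine transporter, which is also on the ATF4 list, rose by 1.51 ± 0.19 and GCLC by 1.05 ± 0.17, while the aldo-keto reductase AKR1C2 fell by -3.92 ± 0.16. The p53 targets rose, 11 of 25 with 0 lower (12 and 1 when adjusted over the list alone), PMAIP1 by 1.98 ± 0.14 (camera adjusted p = 0.00265, adjusted p = 0.203 with an estimated correlation). Heat shock genes fell, 8 of 21 with 1 higher (12 and 1 when adjusted over the list alone), HSPB1 by -2.58 ± 0.18 (camera adjusted p = 0.0174, adjusted p = 0.203 with an estimated correlation). The translocation genes of the endoplasmic reticulum, to which SEC62 belongs, did not pass as a list, with 3 higher and 0 lower of 39 (camera adjusted p = 0.299). SRP72 rose by 0.95 ± 0.11, SEC11C by 0.50 ± 0.13 and EMC8 by 0.42 ± 0.10.

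Immediate early genes rose in the SEC62 knockout, 12 of 26 with 1 lower (15 and 2 when adjusted over the list alone), at camera adjusted p = 2.05e-04 and adjusted p = 0.203 with an estimated correlation. NR4A1, a nuclear receptor, rose by 2.66 ± 0.20, EGR2 by 2.50 ± 0.35, FOS by 2.11 ± 0.30 and FOSB by 2.48 ± 0.65. FOSB was at 1.87 without knockout replicate 3, and its call did not hold without WT replicate 1 (adjusted p = 0.0782) or 2 (0.0661) or knockout replicate 3 (0.0749). Inflammatory genes rose, 10 of 23 with 1 lower (11 and 2 when adjusted over the list alone), the chemokine CXCL1 by 4.93 ± 0.50 and IL32 at -0.82 ± 0.17 (camera adjusted p = 0.0174, adjusted p = 0.203 with an estimated correlation). Mesenchymal and matrix genes fell, 15 of 37 with 6 higher (18 and 6 when adjusted over the list alone), at camera adjusted p = 0.00224 and adjusted p = 0.203 with an estimated correlation. COL1A1 fell from 1495 ± 314 to 15.8 ± 6.12 counts, FBN2, a fibrillin, from 9067 ± 837 to 166 ± 11.3, SPARC by -4.05 ± 0.19 and CD44 by -5.92 ± 0.43 (-5.31 with pseudocount 5). Mitotic genes fell, 11 of 34 with BUB1B higher (12 and 1 when adjusted over the list alone), ASPM by -0.98 ± 0.13 (camera adjusted p = 0.00366, adjusted p = 0.430 with an estimated correlation). Muscle and adipocyte markers moved with these groups: 4 of 7 fell, also when adjusted over the list alone, TNNT2 by -4.37 ± 0.29 (camera adjusted p = 0.0210, adjusted p = 0.430 with an estimated correlation). The muscle call did not hold with only genes of mean 50 or more (0.0945) or a replicate block (0.0578).

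**Figure D3:**
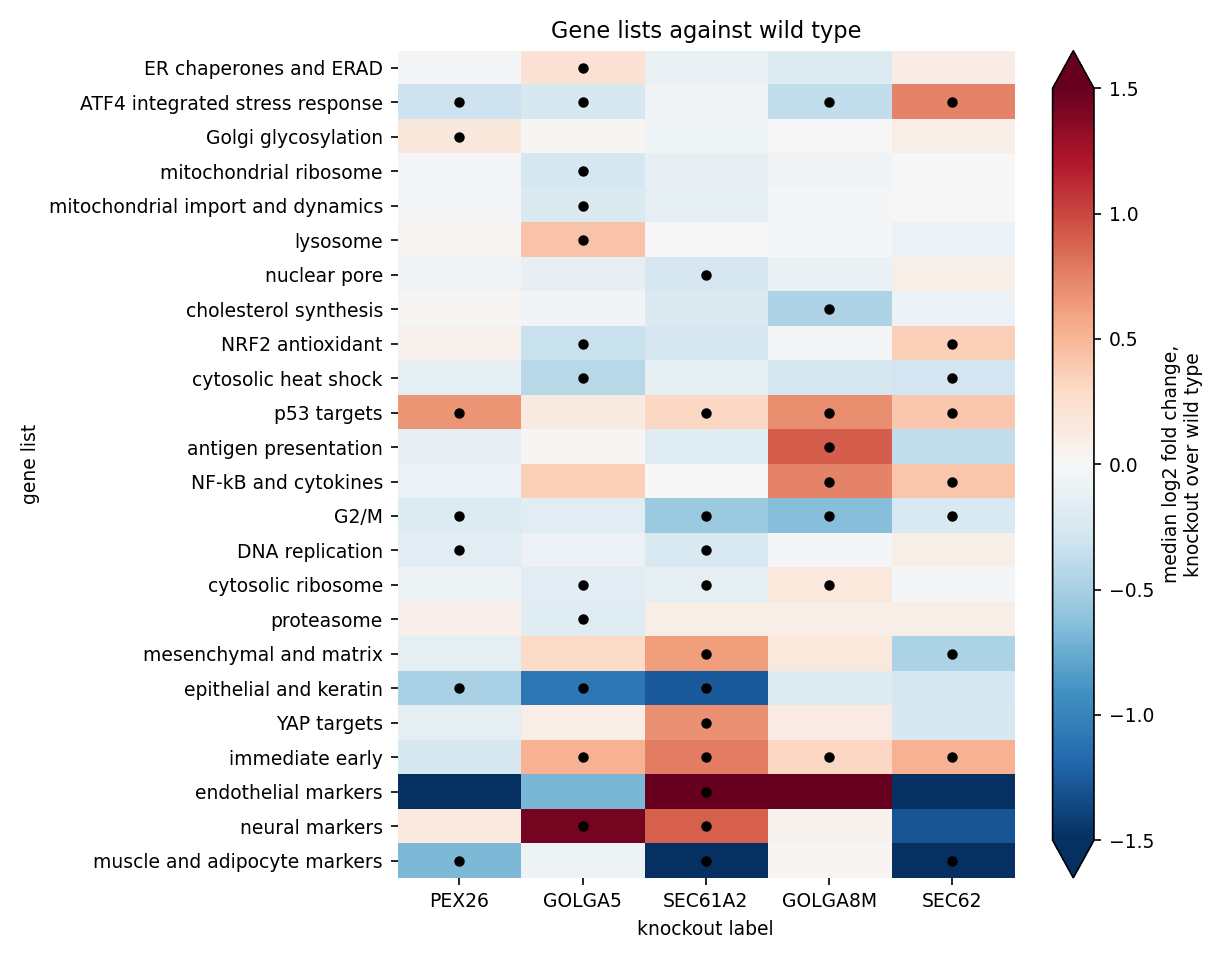
Median log2 fold change of knockout over WT (colour) for each gene list with a camera adjusted p under 0.05 in at least 1 comparison, by knockout label; a dot marks an adjusted p under 0.05. The colour scale ends at 1.5 in either direction, and none of the dots remains with an estimated correlation, where the smallest adjusted p is 0.0951.

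Of the 14853 genes tested in all 5 tables, 112 changed alike in all 5 comparisons, 39 higher and 73 lower. The other 361 genes changed in all 5 went in mixed directions. Of the 473 genes changed in all 5, 112 went the same way, where 29.6 would by chance if directions were independent, an expectation that leaves out the shared WT libraries. Without WT replicate 2, 60 genes changed alike. MMP14, a membrane-bound matrix metalloproteinase, rose in all 5, by 0.68 ± 0.12 in the GOLGA8M knockout up to 3.16 ± 0.11 in the PEX26 knockout. APOE, the apolipoprotein, rose by 0.96 ± 0.20 (GOLGA8M) to 3.36 ± 0.16 (PEX26) and PLEKHH2 by 1.56 ± 0.15 (PEX26) to 3.25 ± 0.14 (SEC61A2 label). LCA5, a ciliary gene, rose by 0.86 ± 0.17 (GOLGA5) to 2.30 ± 0.15 (PEX26). BCL6, a transcriptional repressor, rose by 0.85 ± 0.23 (GOLGA5) to 2.61 ± 0.21 (GOLGA8M) and PCDHGA4, a protocadherin, by 1.50 ± 0.44 (GOLGA8M) to 2.19 ± 0.38 (GOLGA5).

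GAGE2A, GAGE2E, a further member of a family of near-identical genes whose reads may not be told apart, and the long noncoding RNA LINC02287 were listed at 0 in all 15 libraries with a knockout label, with 574 ± 90.3, 339 ± 145 and 40.1 ± 7.07 counts in the WT libraries of the PEX26 table. BMP5 fell to at most 3.54 ± 1.56 counts, the level with the SEC61A2 label, in each of the 5 comparisons. LAD1, which encodes ladinin, fell by -1.18 ± 0.19 (GOLGA8M) to -6.96 ± 0.33 (PEX26), and CHST15 from 579 ± 24.0 to 260 ± 155 counts in the GOLGA5 knockout and to lower levels in the other 4. Several of these calls depended on single libraries. BCL6 lost its call in the GOLGA5 knockout without any 1 of the 6 libraries (adjusted p = 0.0501 to 0.101) and in the PEX26 knockout without any library but knockout replicate 3 (0.0641 to 0.143). It was also lost with no filter in both (0.0651 and 0.0714) and, in the PEX26 knockout, with a mean of at least 50 (0.0515) or a replicate block (0.0793). CHST15 lost its call in the GOLGA5 knockout without any library but knockout replicate 1 (0.0651 to 0.0863). LCA5 lost it in the GOLGA8M knockout without WT replicate 2 (0.0558) or 3 (0.0578) or knockout replicate 2 (0.0526) or 3 (0.0525). PCDHGA4 lost it in the GOLGA8M knockout without WT replicate 1 (0.0722) or 2 (0.104) or knockout replicate 1 (0.126) or 3 (0.107) and with no filter (0.0593). With the SEC61A2 label PCDHGA4 lost it without knockout replicate 1 (0.0501), and in the SEC62 knockout without knockout replicate 1 (0.0613) or 2 (0.0679) or with a replicate block (0.0534).

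**Figure D4:**
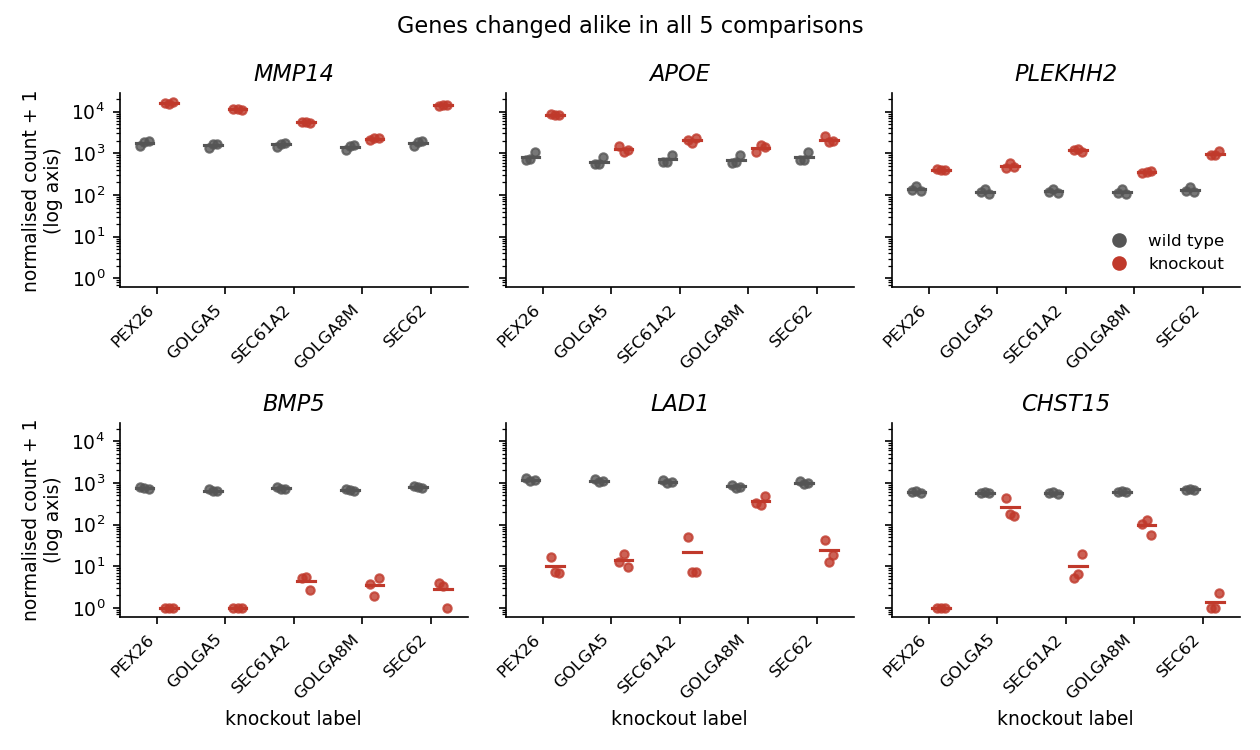
Normalised count plus 1 (log axis) of 6 genes called in the same direction in all 5 comparisons, 1 point per library, with a bar at the mean of the 3 WT (grey) and 3 knockout (red) libraries of each table. MMP14, APOE and PLEKHH2 lie higher and BMP5, LAD1 and CHST15 lower than WT in each knockout.

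The PEX26 and SEC62 knockouts shared 1820 genes changed in the same direction, 687 higher and 1133 lower, and 216 changed in opposite directions, so 89.4% of the genes called in both went the same way. Independent calls would share 189.8 higher and 289 lower. The covariance of the log2 fold changes across genes was 0.676, against at most 0.0477 in 100 simulated draws with shared WT libraries and no changed gene. Pearson r was 0.678 and Spearman rho 0.488 across genes, which are not independent replicates. In these draws, where no gene changed, shared WT libraries alone gave a mean r of 0.499. That value is no baseline for r where many genes changed, so the covariance is the measure to set beside the draws. The GOLGA5 and GOLGA8M knockouts had a covariance of 0.362, with 1099 genes changed in the same direction and 409 in opposite directions. In the PEX26 and GOLGA8M knockouts 632 genes changed in the same direction and 955 in opposite directions (covariance -0.0734). The 3 WT libraries were not split between comparisons. The part of each overlap that comes from the spread between these WT libraries was simulated and not measured. A part that comes from levels particular to the WT cells was neither simulated nor measured.

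**Figure D5:**
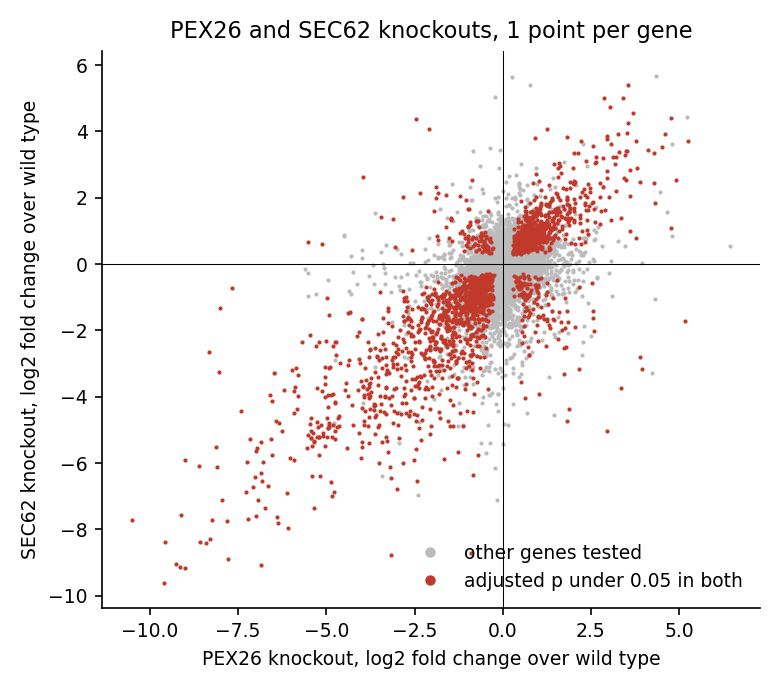
Log2 fold change over WT in the PEX26 knockout (horizontal) and in the SEC62 knockout (vertical), 1 point per gene for the 14853 genes tested in all 5 tables, with genes called in both in red. Of the red points 1820 lie in the quadrants of equal sign and 216 in those of opposite sign.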

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

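All tests in this part of what lies behind a pattern were chosen after the result was seen.

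In each comparison the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes or lists as reported. The real PEX26 split gave 3937 genes and 7 lists, against at most 3 genes and 3 lists in the other splits. For GOLGA5 the real split gave 3409 genes and 12 lists, against at most 2 and 5, and for the SEC61A2 label 5572 and 12, against at most 1 and 5. For GOLGA8M it gave 3823 genes and 8 lists, against at most 1 and 4, and for SEC62 4091 and 9, against at most 1 and 6.

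Some gene lists and genes moved in opposite directions in different knockouts. These differences were not tested, and none of the lists passed with an estimated correlation. ATF4 targets had a median log2 fold change of -0.31 in the PEX26, -0.24 in the GOLGA5 and -0.37 in the GOLGA8M knockout, and of 0.75 in the SEC62 knockout. NRF2 targets had medians of -0.34 in the GOLGA5 and 0.35 in the SEC62 knockout. Cytosolic ribosomal protein genes had medians of -0.16 in the GOLGA5 knockout, -0.14 with the SEC61A2 label and 0.16 in the GOLGA8M knockout, with 0, 3 and 5 of 76 members called when adjusted over the list alone. Mesenchymal and matrix genes had medians of 0.63 with the SEC61A2 label and -0.47 in the SEC62 knockout. For single genes the values are those of calls of at least 3 log2 units, and smaller calls in other comparisons are mostly left out. BCAT1 changed by 3.81 in the PEX26 knockout, by 2.91 in the SEC62 knockout and by -6.12, -4.57 and -9.62 in the GOLGA5, SEC61A2 and GOLGA8M comparisons, the last a fitted value near the floor of detection that depends on the pseudocount. COL1A2 changed by 3.62 in the PEX26 and -10.22 in the GOLGA8M knockout. DHRS2 changed by 4.88 in the GOLGA8M knockout and by -5.53, -4.15 and -5.14 in the PEX26, SEC61A2 and SEC62 comparisons. FN1 changed by 4.04 with the SEC61A2 label and by -5.44 and -3.16 in the GOLGA8M and SEC62 knockouts. ITGB4 changed by 3.44 in the GOLGA8M knockout and by -4.86, -4.43 and -3.96 in the PEX26, SEC61A2 and SEC62 comparisons. NIBAN1 changed by 4.37 with the SEC61A2 label and 5.63 in the SEC62 knockout, and by -3.95 and -3.62 in the GOLGA5 and GOLGA8M knockouts. XACT changed by 5.26 and 3.71 in the PEX26 and SEC62 knockouts and by -4.61 in the GOLGA5 knockout, each with an SE of at least 1.08 (n = 3 per group), values that rest on WT libraries far apart, at 50.7, 0.424 and 10.3 counts in the PEX26 table.

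In the 5 tables, 83 calls of loss were counted, a gene at 100 counts or more in all WT libraries and at 2 or less in all libraries of a knockout, against 16 calls of gain by the mirrored rule. Losses outnumbered gains in the PEX26 (19 and 0), GOLGA5 (17 and 1), GOLGA8M (22 and 0) and SEC62 (18 and 1) knockouts, and with the SEC61A2 label it was the reverse, 7 losses and 14 gains. Lower depth of the knockout libraries is argued against, since a WT library was at most 1.42 times as deep as a knockout library, while loss needs a fall of at least 50-fold. The 83 losses fell on 55 genes, of which 17 were lost in 2 or more knockouts. In 10000 sets of independent draws there were at most 4 such genes. These draws leave out that all losses were counted against the same 3 WT libraries. A gene high only in those is lost in several knockouts at once. The draws also count GAGE2A and GAGE2E, both lost in all 5 knockouts, as separate genes, although their reads may not be told apart. States fixed when each line was grown from a single sorted cell may also be behind the repeated losses, as may the knockouts themselves. With no library labelled as an unedited single-cell line these cannot be told apart.

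The PEX26 and SEC62 knockouts changed many genes alike. Spread between the shared WT libraries as the whole cause is argued against by the covariance of 0.676, against at most 0.0477 in simulated draws. Those draws gave WT and knockout libraries the same mean levels, so they do not cover levels particular to the WT cells. PEX26 knockout cells in the libraries labelled SEC62 knockout are argued against by the PEX26 transcript there, 1.14 times WT on average, where the PEX26 knockout libraries held 0.354 times WT. Gain or loss of whole chromosomes is argued against by the chromosome medians, of which the largest in size was -0.0791. Such levels would enter every pair alike, since all comparisons share the WT libraries. The covariance was -0.0734 for PEX26 and GOLGA8M and 0.0035 for GOLGA8M and SEC62. The highest of the other pairs, GOLGA5 and GOLGA8M, had 0.362. These values argue against levels particular to the WT cells as the whole cause. A common subclone of origin, a part from such levels and an effect of the knockouts stay open and were not tested.

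The SEC61A2 transcript was higher in the libraries labelled SEC61A2 knockout. The authors' correction for transcript length as the whole cause is argued against by an estimated fold of 2.60 ± 0.190 without the length term. The fold as deposited was 3.46 ± 0.252 (SD, n = 3 for both). The length term was inferred, under an assumed form of the correction, from the SEC61A2 level in WT here and in the other 4 tables. Their own length terms were taken as 1 on average. By single tables the estimate was 2.404 to 2.665, a range that the SD leaves out. Copy gain around the gene is argued against by the 10 tested genes within 1 megabase, whose median log2 fold change was -0.19 (-0.186, SD 0.681; the highest, CAMK1D, 1.50). An exchange of labels with the PEX26 or GOLGA5 group is argued against by their transcripts in these libraries, 1.05 ± 0.107 and 0.833 ± 0.0802 of WT, against 0.354 ± 0.0311 and 0.118 ± 0.0250 in their own (SD, n = 3). The transcript is higher in these libraries whatever their label, so an exchange would only move the rise to another knockout. An exchange with the GOLGA8M or SEC62 group cannot be told apart from a rise in the SEC61A2 knockout itself. Neither group showed a fall of its own target, and the lowest SEC61A2 level in them was 0.867 of WT. More transcript from edited alleles was not tested.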

How the results depend on the processing

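The tests of gene lists under another pseudocount, other filters and without single libraries were added after seeing the data; the other alternatives were planned. With pseudocount 5, no filter, a mean of at least 50, TMM factors or a replicate block, each of the 5 counts of changed genes, the count of genes alike and, except as named next, the count of 48 called lists stayed within 1.5 times its value. At an adjusted p under 0.01 and a change of at least 1 log2 unit the counts were 1355 (PEX26), 1067 (GOLGA5), 2110 (SEC61A2 label), 1221 (GOLGA8M) and 1596 (SEC62), with 26 genes alike; this threshold is stricter by construction. Leaving out 1 library, and so testing with fewer, gave 2828 to 3345 genes (PEX26), 2270 to 2823 (GOLGA5, lowest without WT replicate 2), 4449 to 4819 (SEC61A2 label), 2713 to 3059 (GOLGA8M), 2868 to 3309 (SEC62) and 47 to 50 lists. Genes alike were counted again only without each WT library, 60 to 81 (60 without WT replicate 2). Lists called were 0 with an estimated correlation, where 4, 9, 8, 6 and 7 lists per comparison had an unadjusted p under 0.05, and 119 with fry, which does not compare a list with other genes; the cause was not tested. The replicate block gave 3156, 2983, 5096, 3219 and 3232 genes and 78 alike; libraries of equal number did not pair (correlations -0.0643 to 0.0898). Of 210 named gene results, called or not, 170 stayed called or stayed uncalled under all alternatives. Direction was compared only where a call was made. Over all settings 118 values were weaker, 39 of them at the stricter threshold, and 0 reversed. The 1 stronger value was SEC63 with the SEC61A2 label without knockout replicate 3 (limma, adjusted p = 0.0317). Of 48 list calls 0 held under all alternatives, 66 values were weaker and 0 reversed. edgeR and DESeq2 on whole reads were planned but not run, since whole reads could not be recovered. Depth limits genes near 1 read, 0.650 to 1.28 normalised counts.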

Other observations

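The lists that follow did not pass in the comparison they are given for, and their members named here were chosen after their values were seen. Genes of mitochondrial fatty acid oxidation and its regulators moved apart in the PEX26 knockout, 9 higher and 3 lower of 26, and the list did not pass (camera adjusted p = 0.299). PPARG, the adipogenic nuclear receptor, rose from 67.1 to 1234 ± 78.7 counts and ACADM, a dehydrogenase of medium-chain fatty acids, from 1626 ± 43.3 to 3687 ± 295. PPARA fell by -1.15 ± 0.12 and PPARGC1A, at 28.8 counts in WT, was listed at 0. Lysosomal genes, which rose in the GOLGA5 knockout, went both ways in the SEC62 knockout, 5 higher and 15 lower of 59 (camera adjusted p = 0.244), with MITF at -3.14 ± 0.24, TFEB at -1.91 ± 0.21 and NPC1 at 0.64 ± 0.14. The difference between the knockouts was not tested. Interferon-stimulated genes did not pass as a list with the SEC61A2 label, with 6 higher and 2 lower of 23 (camera adjusted p = 0.392). IFIT1 rose by 3.64 ± 0.22 and IFIT2 by 2.67 ± 0.26, and USP18 fell by -2.67 ± 0.23.

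Mesenchymal and matrix genes split in the GOLGA8M knockout, 11 higher and 14 lower of 36 (camera adjusted p = 0.747). THBS1 rose by 2.10 ± 0.08, FBN1 by 2.37 ± 0.09 and COL12A1 by 1.75 ± 0.09, while FN1 fell by -5.44 ± 0.25 and CD44 by -5.65 ± 0.63. Peroxisomal metabolism genes there were 1 higher and 8 lower of 39 (camera adjusted p = 0.0690), with IDH1 at -0.99 ± 0.09. Protein-coding genes of the mitochondrial genome were 4 higher and 0 lower of 11 in the GOLGA8M knockout (camera adjusted p = 0.113) and 0 higher and 4 lower with the SEC61A2 label (camera adjusted p = 0.129). MT-CYB rose by 0.66 ± 0.15 in the first and MT-ND2 fell by -0.95 ± 0.18 in the second. Of 34 genes of glycolysis and hypoxia, 7 rose and 8 fell with the SEC61A2 label (camera adjusted p = 0.697). The glucose transporter SLC2A3 rose from 12.6 to 1985 ± 76.4 counts and PKM, a pyruvate kinase, fell by -0.95 ± 0.10. In the SEC62 knockout the endothelial markers VWF and PECAM1 fell, by -2.19 ± 0.42 and -4.37 ± 0.51, and ESAM rose by 3.23 ± 0.40, with 3 lower and 1 higher of 4 (camera adjusted p = 0.288).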
